A study of Anaxyrus boreas boreas with 48 samples.

How the data were processed

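RNA was isolated from ventral skin and liver of 24 boreal toads and made into stranded libraries from messenger RNA, per the labels' protocols, and sequenced as paired-end reads. The submitters' processing notes name Trimmomatic 0.33, Bowtie2 and RSEM without stating the role or order of each. Per the series' design text the reads were assigned to a de novo transcriptome assembled for the study. The identifiers carry the prefix of the assembler Trinity, and its version is not given in the sources used here. The deposited table holds 1 column of expected counts per library for 204293 assembled genes, that is, the read counts RSEM estimates when reads fit more than 1 transcript, and 95.2% of the values are whole numbers. The values were not normalized by the authors as far as the table shows, since library totals differ. Reads shared between near-identical assembled genes are split by the estimate, and the 204293 genes fall into 154531 clusters of the assembly, so that 1 toad gene can be spread over several lines of the table. How strand was used in counting is not given in the sources used here.

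Columns were matched to samples through the sample descriptions, and 0 columns of values were left unused. Groups, sex, animal and treatment were taken from the labels. Before any averaging, the libraries of each group were compared for duplicates: the smallest chi-square per degree of freedom between 2 libraries of a group was 7.64, so that no pair agreed within sampling noise. Whether skin and liver libraries labelled with 1 animal belong together was checked by correlating deviations from the group means over 25811 genes: 20 of 24 skin libraries matched the liver of their own animal best, where 4 would be expected by chance.

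The expected counts were rounded to whole numbers, genes with low counts were removed in each tissue with filterByExpr by group, and TMM factors were computed. This left 38329 genes in skin and 28916 in liver. Each tissue was fitted with its 24 libraries and 4 groups in edgeR 4.0.16 under R 4.3.3 (estimateDisp and glmQLFit with robust estimation, glmQLFTest), with all groups sharing 1 estimate of the spread. Contrasts were Bd against control within each site, the difference of these effects between sites, and Colorado against Utah controls. Sex was tested with group as an additive term. P-values were adjusted by Benjamini and Hochberg over all genes tested in the tissue and called under 0.05. Standard errors were derived from the log2 fold change and the F statistic. The tests and groups for these 10 comparisons were fixed before the data were examined, as were the alternatives except library totals alone, upper-quartile factors and the fits by sex. A rule fixed at the same time named at most 2 identifiers that rose and 2 that fell, those with the smallest p in the Bd comparison with the most calls. Lists of genes by symbol had been prepared, and they were not used because the files do not pair the identifiers with names.

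Comparisons of single values per library used two-sided exact permutation tests, which with 6 against 6 libraries have 924 arrangements and a smallest p of 0.00217. Groups of liver-typical and skin-typical genes were defined after the data were seen, as genes with a mean log2 CPM of at least 1 in 1 tissue and at least 5 log2 units lower in the other, in the controls of the site not tested. Genes of similar level had a mean log2 CPM of at least 1 in either tissue and less than 1 log2 unit between them in the same controls. They were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and adjusted over 12 tests. Fits by sex used 8 groups of 3 libraries per tissue. Correlations across the 6 inoculated animals of a site were tested over all 720 pairings.

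The steps were tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 changed genes. For Bd against control in Colorado skin, over 38329 genes, 32 of 100 genes changed 2-fold and 84 of 100 changed 4-fold were called, and 2.52% of the calls were false. For the difference of the Bd effect between sites, 10 of 100 genes changed 2-fold and 68 of 100 changed 4-fold were called in skin, and 7 and 63 in liver over 28916 genes. For females against males in liver, 67 and 95 were called, and 6.90% of the calls were false. In these simulations a difference between sites was therefore found less often than a Bd effect of the same size. Only 200 genes were changed in them, while 16298 genes were called in the real Colorado skin. The shares found and the shares of false calls were not tested for so widespread a change and need not hold there.

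Alternatives tried were RLE, upper-quartile and no scaling factors beyond library totals, no filter and a stricter filter on low counts (CPM of at least 1 in at least 6 libraries), DESeq2 1.42.0 with its own filtering, fits without the robust steps, with sex as a covariate, with the replicate number as a factor, with only the groups compared, by sex, on counts summed to assembly clusters, with a minimum 2-fold change, and without each library in turn. Depth limits single genes: with totals of 10632826 to 21003900, 1 CPM corresponds to 10.6 to 21.004 counts in a library.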

Results

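Gene expression was measured by RNA sequencing in ventral skin and liver of laboratory-reared boreal toads (Anaxyrus boreas boreas) from Colorado and Utah. Part of the animals had been inoculated with Batrachochytrium dendrobatidis (Bd), the chytrid fungus that infects the keratinised skin of amphibians and causes chytridiomycosis. Inoculated toads were held for 24 hours with 1000000 zoospores, the swimming infective stage, and control toads were held for the same time in the carrier solution alone. Tissue was taken on day 34. The 48 libraries came from 24 animals, each of which gave 1 skin and 1 liver library, and formed 8 groups of 6 (3 females and 3 males each). The toads of a site were siblings of 1 clutch, so that site and clutch cannot be separated and the p-values measure the spread between siblings. Library totals ran from 10632826 to 21003900 estimated counts.

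The deposited table lists 204293 genes of a de novo transcriptome assembly by assembly identifiers. The files do not pair these identifiers with gene names, so the results are given for groups of assembled genes, and 4 identifiers are followed through the comparisons. A gene is called where edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05.

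In skin, the first principal component held 38.5% of the variance and placed the 6 Colorado Bd libraries (between -179 and -69.3) apart from all 12 control libraries (between 53.8 and 100.1). The Utah Bd libraries ranged from -89.8 to 5.47, below all controls, and 2 of the 6 lay within the Colorado Bd range. In liver, the first component held 34.4% of the variance. The Colorado Bd females had values from -170.3 to -159.9 and the Colorado Bd males from -79.8 to -25.1, while all other libraries lay between -12.3 and 72.4.

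**Figure D1:**
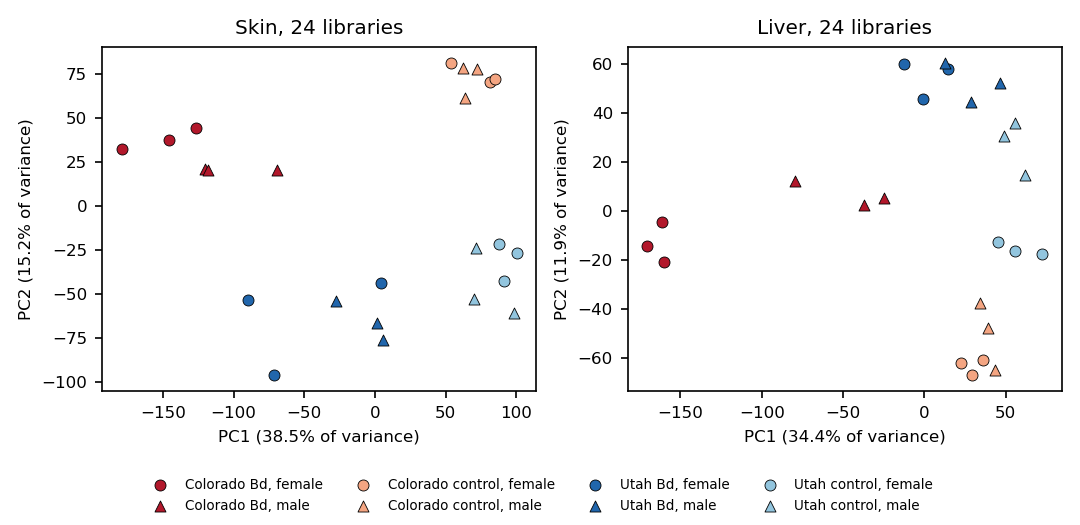
First 2 principal components of log2 CPM (counts scaled to a library total of 1000000) in the 24 skin libraries (left) and the 24 liver libraries (right). Each point is 1 library, colour gives the site and treatment, circles are females and triangles are males. On the first component the Colorado Bd livers of females (-170.3 to -159.9) lie farther from the controls than those of males (-79.8 to -25.1).

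The basic question of the challenge was which genes differ between inoculated and control toads of a site. In Colorado skin 16298 of 38329 tested genes differed, 42.5% of those tested. Of these, 8716 were higher after inoculation, with a median log2 fold change of 1.06, and 7582 were lower, with a median of -0.99. At least 8-fold rises numbered 929 and falls of that size 261. Genes typical of skin, taken as those at least 5 log2 units above liver in the controls of the other site, fell more often than they rose: 690 of 1692 fell and 333 rose, with a median log2 fold change of -0.41. Camera with a preset correlation placed this set below the other genes (adjusted p = 0.000119), and the call was lost with an estimated correlation (adjusted p = 0.244 with an estimated correlation). The 100 most abundant genes of skin took 41.8% ± 4.91 (SD, n = 6) of the counts in Colorado controls and 32.2% ± 3.47 (SD, n = 6) after inoculation, so that the share fell by 9.57 percentage points (two-sided exact permutation test, p = 0.00649, adjusted p = 0.0130 over 4 tests), and 39 of these genes fell while 8 rose. With upper-quartile scaling, chosen after the data were seen, 6584 genes were higher and 10791 lower, so the balance of rises and falls in Colorado skin depends on the scaling. Requiring a 2-fold change left 8364 genes.

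The assembled gene TRINITY_DN138725_c3_g1 rose from 2.47 ± 0.3004 to 30.4 ± 6.90 counts per 1000000 counts of the library (CPM; SD, n = 6) in Colorado skin, a log2 fold change of 3.58 ± 0.251 (SE; edgeR adjusted p = 3.25e-09). TRINITY_DN148436_c1_g3 rose from 0.105 ± 0.0906 to 19.7 ± 6.66 CPM, a log2 fold change of 7.35 ± 0.513 (SE). Its Colorado controls held 11 counts in all 6 libraries together. TRINITY_DN138038_c2_g1 fell from 49.3 ± 9.10 to 9.24 ± 2.22 CPM (log2 fold change -2.47 ± 0.173, SE), and TRINITY_DN153835_c3_g1 fell from 55.0 ± 9.24 to 12.2 ± 2.26 CPM (log2 fold change -2.23 ± 0.157, SE). The identifiers were taken by the smallest p in this comparison, so these sizes are selected ones.

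In Utah skin 6817 genes differed between inoculated and control toads, 4335 of them higher and 2482 lower, with median log2 fold changes of 1.08 and -0.99. All 4 followed genes changed in the direction seen in Colorado. TRINITY_DN138725_c3_g1 rose by a log2 fold change of 3.26 ± 0.250 and TRINITY_DN148436_c1_g3 by 3.28 ± 0.418, and TRINITY_DN138038_c2_g1 and TRINITY_DN153835_c3_g1 changed by -1.84 ± 0.168 and -1.48 ± 0.153 (SE; n = 6 per group). Genes typical of skin again fell more often than they rose (310 against 209 of 1744; camera adjusted p = 0.00459, and adjusted p = 0.281 with an estimated correlation). Of the 1040 genes typical of liver, 250 were tested in skin, and 121 were called as higher and 1 as lower (camera adjusted p = 7.45e-06, and adjusted p = 0.465 with an estimated correlation). This rested on 1 library: the inoculated Utah skin replicate 2 held 18410 CPM of liver-typical genes while the other 5 held 799 to 1844, and without it 30 rose and 5 fell. The share of counts in the 100 most abundant genes did not differ measurably in Utah skin (difference 0.219 percentage points, two-sided exact permutation test, p = 0.961). Counts were 6597 with upper-quartile scaling, of which 3368 were higher and 3229 lower. Fitting the 12 Utah libraries alone gave 3996 genes.

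The Bd effects of the sites were then compared, with no control library in common. In skin 3624 genes rose in both, where independent lists would share 986, and 1762 fell in both, where independent lists would share 491. The opposite direction was seen for 7 genes. Across genes, which are not independent replicates, the log2 fold changes of the sites had a Pearson correlation of 0.777 and a Spearman correlation of 0.716. Genes called as higher in Utah skin, numbering 4335, had a median log2 fold change of 1.17 in Colorado, where 97.7% had the same sign. Genes called as higher in Colorado skin had a median of 0.55 in Utah, where 91.8% had the same sign. Selection is expected to inflate the median at the site that chose the genes. The genes called as higher in Utah nevertheless had a median of 1.08 there, below their median in Colorado.

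Whether inoculation changed a gene differently in the 2 sites was tested with the interaction of site and treatment, the comparison the study makes between toads it calls tolerant and susceptible. The labels do not state which site is which. In skin the effect differed for 33 of 38329 genes, 19 of them with a higher log2 fold change in Colorado and 14 with a lower one, and 5892 passed an unadjusted p under 0.05. The change was larger in Colorado for 32 of the 33. The 19 had a median log2 fold change of 3.05 in Colorado and 0.03 in Utah. They were chosen by this difference in the same libraries, which widens the gap between the medians. Among all genes called as higher in Colorado skin the Utah median was 0.55. One of the followed genes, TRINITY_DN148436_c1_g3, was among them, with a difference of 4.07 ± 0.690 (SE; edgeR adjusted p = 0.0443). Its Utah controls held 0.546 ± 0.298 CPM and its Colorado controls 0.105 ± 0.0906 CPM (SD, n = 6). This count of 33 is not stable: it was 819 with DESeq2 and 829 with no filter on low counts. Leaving out any 1 of the 24 libraries moved it by more than 1.5 times, to between 0 and 700 (without the inoculated Utah replicate 6). It was 0 without the inoculated Colorado replicate 2 or 4 or the Colorado control replicate 2, 4 or 6. The same held without the inoculated Utah replicate 2, 3 or 5 or the Utah control replicate 1 or 2, each left out singly.

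In Colorado liver 10646 of 28916 tested genes differed after inoculation. Of these, 5984 were higher, with a median log2 fold change of 1.13, and 4662 were lower, with a median of -1.02. Genes typical of liver fell more often than they rose: 324 of 1015 fell and 165 rose (camera adjusted p = 0.000271, and adjusted p = 0.465 with an estimated correlation). Of the 1692 genes typical of skin, which are low in these livers, 247 were tested, and 83 rose and 28 fell (camera adjusted p = 0.0134, and adjusted p = 0.281 with an estimated correlation). Low genes can pass the filter through the inoculated livers alone, which favours rises. The summed level of the 1692 was 1848 ± 957 CPM in inoculated and 526 ± 50.7 CPM in control livers (SD, n = 6; two-sided exact permutation test, p = 0.00217, the smallest this design can give, adjusted p = 0.0173 over 8 tests). The 100 most abundant genes of liver lost share, from 46.2% ± 1.96 of the counts in controls to 35.97% ± 3.98 after inoculation (SD, n = 6; exact permutation p = 0.00217, adjusted p = 0.00866 over 4 tests), and 63 of them fell while 12 rose. Scaling by library totals alone, tried after the data were seen, moved the median log2 fold change of all genes from 0.05 to 0.53 and called 11853 genes as higher and 1433 as lower. Upper-quartile scaling turned the balance the other way, to 4901 higher and 5447 lower. The changes above are therefore relative to the bulk of the genes.

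Fewer genes were called in Utah liver. The count was 925, with 572 higher (median log2 fold change 1.40) and 353 lower (median -0.83). With library totals alone 1806 were higher and 71 lower. The count moved by more than 1.5 times without any 1 of 8 libraries: it was 611, 182 and 296 without the inoculated replicates 2, 4 and 6, and 1567, 612, 385, 191 and 178 without the control replicates 1, 2, 3, 4 and 6. The 100 most abundant genes took 44.2% ± 2.94 of the counts in controls and 38.7% ± 4.32 after inoculation (SD, n = 6; two-sided exact permutation test, p = 0.0325, adjusted p = 0.0433), although 2 of them were called as higher and 1 as lower. Genes typical of liver showed no shift (58 rose and 36 fell of 1040; camera adjusted p = 0.809), and genes measured at similar levels in both tissues tended to fall (216 against 74 of 7694; camera adjusted p = 2.72e-06, and adjusted p = 0.00387 with an estimated correlation). Such genes showed no measurable shift in Colorado liver (2032 rose and 2019 fell of 10760; camera adjusted p = 0.208) and rose more often than they fell in Colorado skin (2953 against 1789; adjusted p = 0.0548) and Utah skin (1027 against 316; adjusted p = 0.0345, and adjusted p = 0.244 with an estimated correlation). Of the genes called in Utah liver, 424 also rose and 292 also fell in Colorado liver, where independent lists would share 118 and 56.9, and 0 went in opposite directions. The genes called as higher in Utah had a median log2 fold change of 1.28 in Colorado. The converse was weaker: of the 5984 genes called as higher in Colorado liver, 77.1% had the same sign in Utah, with a median of 0.27, and 7.09% were called there. Across genes the log2 fold changes of the sites had a Pearson correlation of 0.546 and a Spearman correlation of 0.505.

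The Bd effect in liver differed between the sites for 656 genes, with 502 higher and 154 lower in Colorado relative to Utah. The change was the larger one in Colorado for 639 of the 656. The 502 genes had a median log2 fold change of 1.86 in Colorado and 0.02 in Utah, and the 154 had medians of -1.70 and -0.06. These genes were chosen by this difference in the same libraries, which widens the gap between the medians. Among all genes called as higher in Colorado liver the Utah median was 0.27. The tally of 639 and the medians of the 502 and 154 genes were made for the main fit alone. The number called has to be read with care, since leaving out single libraries moved it to between 3 (without the inoculated Utah replicate 3) and 2769 (without the inoculated Colorado replicate 6), by more than 1.5 times for 19 of the 24. It was 2027 with DESeq2 and 41 with the replicate number as a block. Fitted by sex, after the data were seen, it was 4321 in females alone (2172 higher and 2149 lower) and 1 in males alone, where 2632 passed an unadjusted p under 0.05. With library totals alone 1294 genes were higher and 82 lower, and with upper-quartile scaling 244 were higher and 134 lower.

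The size of the response was also summarised per animal, as the mean log2 difference from the own site's control mean over called genes, each taken with the sign of its change. Over the 6817 genes called in Utah skin, the inoculated Colorado toads had a mean of 1.35 and the inoculated Utah toads 1.14 (two-sided exact permutation test, p = 0.115, adjusted p = 0.153 over 4 tests). Over the 925 genes called in Utah liver the means were 1.26 and 1.25 (exact permutation p = 0.875, adjusted p = 0.875). Over the 16298 genes called in Colorado skin the means were 1.23 and 0.629 (exact permutation p = 0.00649, adjusted p = 0.0130), and over the 10646 genes called in Colorado liver 1.18 and 0.372 (exact permutation p = 0.00217, adjusted p = 0.00866). The genes and signs of a set come from the same libraries that are then scored, which favours the site that chose it. The p-values over the Colorado sets therefore do not test a difference between sites. The sets called in Utah, where the choice favours Utah, did not give higher Utah means. The differences over the genes called in Utah, 0.213 in skin and 0.02 in liver, were within the spread between animals.

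Skin and liver were taken from the same animals. Among 25811 genes tested in both tissues, 4457 were called in the same direction in Colorado skin and liver and 573 in opposite directions. The Bd effects of the tissues had a Pearson correlation of 0.430 across genes. In Utah 323 genes were called in the same direction and 14 in opposite directions, with a Pearson correlation of 0.312. Independent lists would share 1433 rises and 688 falls in Colorado, where 2842 and 1615 were seen. For Utah they would share 58.5 rises and 16.6 falls, and 288 and 35 were seen. Part of any excess can come from the shared animals.

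Toads of the sites also differed without inoculation. In control skin 3943 genes differed between Colorado and Utah, 1765 higher and 2178 lower in Colorado, and the falls were larger (1541 of at least 2-fold against 499 such rises). In control liver 560 genes differed, 232 higher and 328 lower in Colorado, and 142 of the latter differed by at least 8-fold. Of the genes tested in both tissues, 250 were called in the same direction and 6 in opposite directions. The followed gene TRINITY_DN148436_c1_g3 was lower in Colorado control skin (log2 fold change -2.24 ± 0.603, SE; edgeR adjusted p = 0.0191). In skin the count rose to 6529 when the control libraries were fitted alone and fell to 2587 without the Utah control replicate 2. In liver, library totals alone gave 154 higher and 622 lower.

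Sex was balanced within each group. Over all 24 livers 184 genes differed between females and males, 133 higher and 51 lower in females. The count was 119 without the inoculated Colorado replicate 1, 435 without the Utah control replicate 4, 486 with DESeq2, 74 with the replicate number as a block and 90 without a group term. Replicate numbers largely follow sex, so that block leaves less of the contrast between the sexes to test. With library totals alone the balance turned to 85 higher and 144 lower in females. Of the 133, 38 were at least 32-fold higher in females. In Colorado these 38 genes together held 70170 CPM on average in control females (18310 to 141200, n = 3) and 3527 CPM in inoculated females (1890 to 6493, n = 3). After inoculation 22 of the 38 were called as lower in Colorado females and 0 as higher, with a median log2 fold change of -5.09. In Colorado males the median was -3.57, with 0 called. Colorado control males held 2382, 79.7 and 37.3 CPM and inoculated males 98.1, 135.6 and 108.6 CPM. A fall of the sum in males therefore rests on the control replicate 1 with 2382 CPM. The 38 were chosen over all livers, and Colorado control females had the highest mean, so the choice favours a fall there. In Utah the inoculated females held 24760 CPM (12530 to 34930, n = 3). The Utah control females held 76600, 311.7 and 22.2 CPM, so the spread there covers the range of both sexes, and 0 of the 38 were called in Utah females. All males had between 14.2 and 2382 CPM. The difference of the Bd effect between the sexes was called for 0 of the 38 genes in Colorado. With 3 animals in each of these cells, a permutation test of the sums cannot go below 0.1. In skin 5 genes differed between the sexes, 1 higher and 4 lower in females, with 3541 at an unadjusted p under 0.05. The skin count was 153 with DESeq2, 636 with no filter and 2686 with library totals alone, where 2606 were lower in females. Leaving out single skin libraries gave 2 to 52 genes.

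The 3 females and 3 males of each group were then fitted as separate groups, a comparison added after the principal components had been seen. In Colorado liver the Bd effect differed between females and males for 2991 genes. Of these, 1704 had a higher and 1287 a lower log2 fold change in females. The 1704 had a median log2 fold change of 1.60 in females and 0.01 in males, and the 1287 had medians of -2.04 and -0.02. These genes were chosen by this difference in the same livers, which widens the gap between the medians. Within a sex, 12402 genes were called in Colorado females and 2189 in Colorado males, 3358 in Utah females and 0 in Utah males, where 1149 passed an unadjusted p under 0.05. The sexes were taken as labelled, and the Utah results by sex include the 2 control females with 22.2 and 311.7 CPM of the genes above. In Utah liver the difference between the sexes was called for 0 genes with edgeR (2771 at an unadjusted p under 0.05), and the difference between sites of that difference for 1190. The Bd effect in liver differed between the sites for 6049 genes in females and for 0 in males (edgeR, 2019 at an unadjusted p under 0.05). In skin the Bd effect differed between the sexes for 22 genes in Colorado and for 0 in Utah, where 3549 passed an unadjusted p under 0.05. More genes were called in females in skin too: 13783 against 6502 in males in Colorado and 6666 against 515 in Utah. The Bd effect in skin differed between the sites for 766 genes in females and for 0 in males, where 3315 passed an unadjusted p under 0.05. Leaving out single Colorado livers changed the 2991 to between 1790 and 3309. The lowest counts were 1790 without the inoculated male of replicate 6 and 1977 without the control female of replicate 4.

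**Figure D2:**
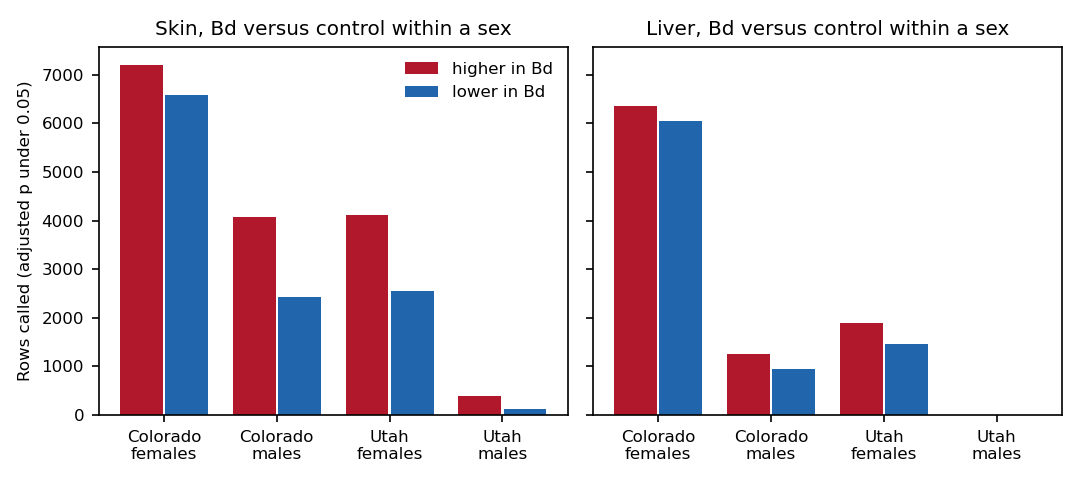
Number of genes called as higher (red) or lower (blue) after inoculation within each sex, in skin (left) and liver (right), from fits with 3 animals per site, treatment and sex. In liver 12402 genes were called in Colorado females, 2189 in Colorado males, 3358 in Utah females and 0 in Utah males.

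A de novo assembly made from infected animals can hold transcripts of the fungus as well as those of the toad. Assembled genes were therefore chosen that had a count of 0 in all 6 Colorado control skins and were detected in at least 4 of the 6 inoculated ones with at least 10 counts in all, and they were measured at the other site. The 421 genes chosen in Colorado summed to 466 ± 440 CPM in inoculated and 22.3 ± 9.50 CPM in control Utah skin (SD, n = 6; two-sided exact permutation test, p = 0.00217, the smallest this design can give). All 6 inoculated libraries (158 to 1330 CPM) lay above all 6 controls (11.6 to 34.0 CPM). The 72 genes chosen in Utah summed to 234 ± 168 CPM in inoculated and 1.02 ± 0.301 CPM in control Colorado skin (SD, n = 6; exact permutation p = 0.00217). Part of the chosen genes were also found in liver. Of the 421, 59 to 95 were detected in each inoculated Utah liver and 42 to 67 in each control one. Of the 72, 20 to 29 were detected in each inoculated Colorado liver and 13 to 15 in each control one. The 421 genes reached 1418 ± 478 CPM in inoculated and 509 ± 180 CPM in control Utah livers, and the 72 genes reached 1081 ± 194 and 311 ± 80.9 CPM in inoculated and control Colorado livers (SD, n = 6).

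**Figure D3:**
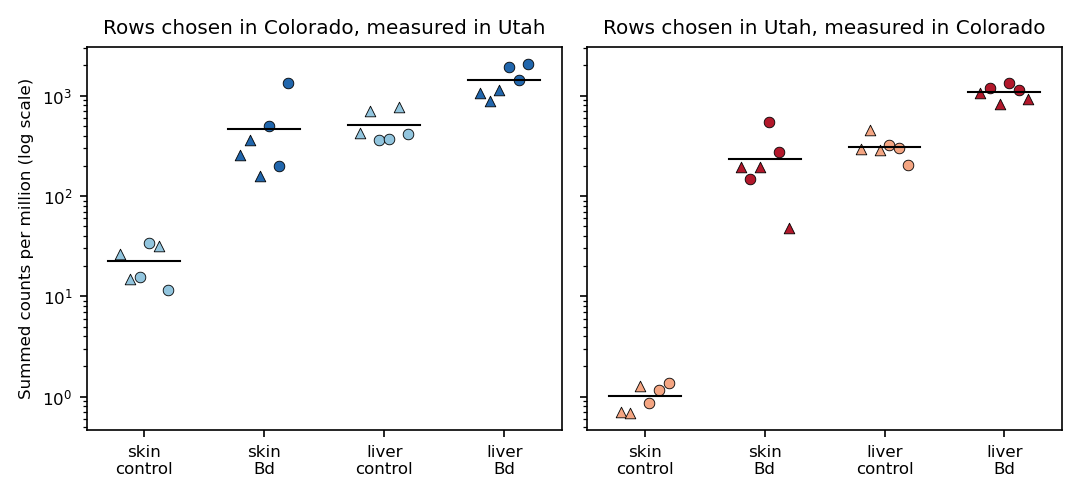
Summed CPM, on a log axis, of genes found only after inoculation in the skin of 1 site, measured in each library of the other site. Each point is 1 library (circles females, triangles males) and lines are group means. For genes chosen in Colorado, inoculated Utah skin (158 to 1330 CPM) lies above control Utah skin (11.6 to 34.0 CPM), and the livers of both Utah groups hold more than the control skin.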

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

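The comparisons by sex, the groups of liver-typical and skin-typical genes and the test of the sexes among control livers were chosen only after results had been seen. Splits of the samples were drawn 100 at a time, the real split included.

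The Bd effect in Colorado liver differed between females and males for 2991 genes, and this difference itself differed between the sites for 1190. In 4 of 100 splits of the sexes within the Colorado groups, the real one included, as many genes were called. The highest other split gave 3171 after exchanging 2 libraries. These splits also exchanged control livers, while the comparison was added after the inoculated livers had been seen to divide along sex. A low share among these splits therefore does not make chance unlikely. Library depth is argued against, since 2687 genes were called after every liver library had been thinned to the smallest total, 10632826. For a sex difference already present in control livers, the first test, a count of calls between female and male Colorado controls (5 genes), decides nothing, since with 3 against 3 livers even the 38 female-high genes, with a median log2 difference of 6.74, gave 0 calls. It was replaced by the share of each difference that lies in the controls. Over the 2991 genes this share had a median of 0.117 (quartiles 0.00765 and 0.236), where at least 0.5 would be needed, which argues against it as the main part of the difference. A single response shared by the sites and merely stronger in some animals would give differences with the sign of the Utah liver effect, and 47.0% of the called genes had that sign, against 50.8% of all tested genes. The effect was the larger one in females for 94.8% of the called genes. Their female-minus-male difference had the sign of the male effect for 51.0%, where a weaker male form of the same response would give more. Choosing genes by that difference lowers this share, and over all tested genes the effects of the sexes had a Pearson correlation of 0.607. A response of Colorado alone that was stronger in the females is therefore neither excluded nor shown. What stays open is sex itself, or any other property that separates the 3 inoculated females from the 3 males, a division of 6 animals that has a chance of 0.1 of falling along sex.

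The genes found only after inoculation in Colorado skin reached 1330 CPM in the inoculated Utah skin replicate 6, far from the other 5 libraries of its group (158 to 494.5 CPM). Without it the mean of that group was 294 CPM instead of 466 CPM, against 22.3 CPM in controls (exact permutation test with 5 against 6 libraries, p = 0.00217). Among these genes, 231 were also at 0 in all Colorado livers. In Utah they had 3257 counts in inoculated skin, 228 in control skin and 65 in liver, so that 91.75% lay in inoculated skin (exact 95% interval 90.8% to 92.6%, counting error only), which is under the 95% that fungal transcripts alone would need and above the 80% that would argue against them. The reverse choice, genes at 0 in inoculated Colorado skin and in livers and present in control skin, gave 262 genes, or 113 for each 100 of the first kind, so that toad genes of low abundance could give as many, although 75.7% of the Utah counts of these lay in control skin. The 31 genes chosen likewise in Utah had 99.1% of their Colorado counts in inoculated skin, while the reverse choice in Utah gave 125 genes, or 403 for each 100, with 78.0% of their Colorado counts in control skin. Transcripts of the fungus and of the toad cannot be told apart here, because the identifiers carry no sequence or name, and both may contribute.

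Liver-typical genes summed to 18410 CPM in the inoculated Utah skin replicate 2 and to 799 to 1844 CPM in the other 5 libraries of its group. If the excess came from liver RNA, each abundant liver gene would be raised by about the same share of its liver level. Of the 50 most abundant liver-typical genes, 92% had an excess within 3-fold of the median share, which was 3.84% of the level in inoculated Utah livers. This is consistent with a few percent of liver RNA in that library, as a hypothesis, and whether it entered at dissection or later was not tested. Without this library the liver-typical genes called as higher in Utah skin numbered 30 instead of 121, while 6177 instead of 6817 genes were called in all, and the genes found only after inoculation in Colorado still averaged 488 CPM in inoculated Utah skin against 22.3 CPM in controls (exact permutation test with 5 against 6 libraries, p = 0.00217).

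The library total of the Utah skin control replicate 3 was 20633801, against 14114410 to 15120687 in the other 5 of its group. In all, 3 of 64 groups of 6 values held a value this far from the others, and chance alone gives about 1 in 20.

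The Bd effect differed between the sites for 33 genes in skin. As many were called in 2 of 100 splits, the real one included, and the highest other, 7054, exchanged 12 libraries, that is, inoculated and control at 1 site as a whole, which turns the contrast into the sum of both effects. In liver the difference was 656 genes against 11 in the highest other split, with 1 of 100 as large. These splits mix inoculated and control libraries within a group, so the Bd effects widen the spread and the median other split called 0 genes. They would call few genes with or without a site difference. Whether chance gave the 33 or the 656 is therefore not decided. The log2 difference of TRINITY_DN148436_c1_g3 between the sites was 4.07. The Bd effect in Colorado skin differed between the sexes for 22 genes.

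For the other comparisons, the real split was compared with the highest other of 100. A chance split is unlikely for Bd against control in Colorado skin (16298 against 6757), Utah skin (6817 against 2458), Colorado liver (10646 against 3238) and Utah liver (925 against 148). The same holds for controls between sites in skin (3943 against 321) and liver (560 against 22) and for the sexes in liver (184 against 4). Each had 1 of 100 splits as large, the lowest share that 100 splits can give, so chance is not excluded. For the sexes in skin 2 of 100 splits gave as many as the real 5 genes, with 5 in the highest other.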

How the results depend on the processing

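The fits by sex, library totals alone, upper-quartile factors and leaving out libraries for the genes found only after inoculation were chosen after the data were seen, as were all alternatives for the difference between the sexes in Colorado liver. Prepared gene lists, and the camera alternative for them, were not run because the identifiers carry no names. All 4 followed genes kept their direction and call in Colorado skin under each of 36 alternatives. The summed level of the genes found only after inoculation stayed higher in inoculated Utah skin under 3 other choices of genes or scaling, with differences of 93.4 to 515 CPM, and without each Utah skin library in turn (271 to 506 CPM). For the counts of called genes, RLE factors, fits without the robust steps, the stricter filter and sums over assembly clusters changed none of the comparisons they were run for (10, and 8 for the sums, which left out the sexes) by more than 1.5 times. Where counts moved, the cause was not tested. By design, fits by sex or with only the groups compared use fewer libraries and a minimum fold change removes genes. A block by replicate number, which largely follows sex, leaves less of the contrast between the sexes.

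In the order Colorado skin, Utah skin, Colorado liver and Utah liver, a minimum 2-fold change left 8364, 3559, 5987 and 564 genes for Bd against control, and 2040 for control skin between sites. Females alone gave 10108 and 2978 in skin and 1867 in Utah liver, 11 and 4321 for the site difference in skin and liver, and 216 and 261 between controls. Males alone gave 8761, 1385, 2847 and 1, then 8 and 1 for the site difference and 1619 and 315 between controls. DESeq2 gave 1904 in Utah liver, 819 and 2027 for the site difference in skin and liver, 957 between control livers, and 153 and 486 between the sexes in skin and liver. No filter gave 1433 in Utah liver, 829 and 1593 for the site difference, 6599 and 1293 between controls, and 636 and 1335 between the sexes. Library totals alone gave 4492 in Utah skin and 1877 in Utah liver, 87 and 1376 for the site difference, 2582 between control skins and 2686 between the sexes in skin, and for the sex difference in liver 85 were higher and 144 lower in females. They moved the median log2 fold change of all genes by 0.48 in Colorado liver, 0.27 in Utah liver, 0.20 for the site difference in liver, -0.26 between control livers, -0.24 and -0.13 between the sexes in skin and liver and 0.12 for the site difference in skin, where 79 were higher and 8 lower. Upper-quartile factors gave 378 for the site difference in liver (median moved by -0.13), moved the median by -0.18 in Colorado skin and -0.11 in Colorado liver, and turned the balance of the skin site difference to 13 higher and 15 lower. The 2 groups alone gave 3996 in Utah skin, 392 in Utah liver and 6529 between control skins. Sex as a covariate gave 62 for the skin site difference. Without a group term the sexes differed for 0 genes in skin and 90 in liver. Genes called at both sites in the same direction fell from 5386 to 2412 in skin and from 716 to 63 in liver at an adjusted p under 0.01.

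Replicate numbers are shared by the groups, and they did not pair inoculated with control animals: of 6 pairs per site and tissue, 1 or 2 had correlated deviations over 0.1, and a library matched its own number best in 0 to 3 of 6. With the replicate number as a replicate block the counts were 15659, 5601, 9996 and 498 for Bd against control in the order above, 5 and 41 for the site difference, and 0 and 74 between the sexes in skin and liver. Replicate 1 was male and replicate 4 female in every group, and each other number held mostly 1 sex. The block therefore leaves less of the contrast between the sexes to test, by design.

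Leaving out each library in turn gave 14635 to 17290 genes in Colorado skin, 4793 to 7609 in Utah skin, 8945 to 11955 in Colorado liver and 178 to 1567 in Utah liver. The ranges were 0 to 700 and 3 to 2769 for the site difference in skin and liver, 2587 to 4768 and 450 to 635 between controls, and 2 to 52 and 119 to 435 between the sexes. For the difference of the Bd effect between the sexes in Colorado liver the range was 1790 to 3309. That count was 3019 with RLE factors, 2824 with library totals alone (2118 higher and 706 lower) and 2687 after thinning. In simulated counts 10 and 7 of 100 2-fold differences between sites were found in skin and liver, and 68 and 63 of 100 4-fold ones, so most 2-fold differences of this kind would be missed. Thinning was run for no other comparison, so what depth limits there was not tested.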

Other observations

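The sums of tissue-typical genes, the look at single females and the definition of genes found in 1 site were chosen only after results had been seen. Genes typical of the other tissue rose in sum after inoculation in Colorado skin, in Utah liver and, as reported above, in Colorado liver, and no such difference was measured in Utah skin (1142 ± 251 CPM in controls and 4009 ± 7066 CPM after inoculation, SD, n = 6; exact permutation p = 0.515, adjusted p = 0.589), where the mean after inoculation rests on replicate 2 with 18410 CPM and the other 5 libraries averaged 1129 CPM. In Colorado skin liver-typical genes summed to 799 ± 108 CPM in controls and 1331 ± 289 CPM after inoculation (SD, n = 6; two-sided exact permutation test, p = 0.00649, adjusted p = 0.0173 over 8 tests), although similar numbers of the 250 tested ones rose and fell (45 and 32). In Utah liver the 1744 skin-typical genes summed to 805 ± 172 CPM in controls and 1235 ± 301 CPM after inoculation (SD, n = 6; exact permutation p = 0.00649, adjusted p = 0.0173). Of these, 303 were tested, with 12 called as higher and 0 as lower. CPM is scaled to library totals, under which all tested Utah liver genes had a median log2 fold change of 0.28. Part of the rise in sum can therefore come from scaling. The fall of the abundant skin-typical genes in sum passed no threshold in Colorado skin (187600 ± 20500 CPM in Colorado controls and 167600 ± 19450 CPM after inoculation, SD, n = 6; exact permutation p = 0.110, adjusted p = 0.177) or in Utah skin (179300 ± 28290 and 153600 ± 7866 CPM; exact permutation p = 0.0671, adjusted p = 0.134).

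The 38 genes that were at least 32-fold higher in female liver did not mark every female. In the Utah control group replicate 3 held 76600 CPM, replicate 6 held 311.7 CPM and replicate 4 held 22.2 CPM, which lies within the range of the Utah males (14.2 to 111.8 CPM). Leaving out that replicate 4 raised the number of genes that differed between the sexes in liver from 184 to 435.

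A hypothesis was that inoculated animals with a larger response in skin also have a larger one in liver. The response was the mean signed log2 difference over genes called at the other site. Across the 6 inoculated Colorado toads the skin and liver values had a Pearson correlation of -0.0547 (exact permutation over 720 pairings, p = 0.931, adjusted p = 0.931 over 6 relations) and a Spearman correlation of 0.143 (exact p = 0.803, adjusted p = 0.964), and r was 0.04 without the 2 toads farthest from the median of the skin value. Across the 6 Utah toads the correlations were 0.542 (exact p = 0.271, adjusted p = 0.542) and 0.371 (exact p = 0.497, adjusted p = 0.746), and r was 0.143 without the 2 farthest. Before r was seen, an r under 0.3 had been set as the value that would argue against the hypothesis, and Colorado met it. The further demand that the 95% interval end below 0.7 was added after r was seen, because a point value from 6 animals excludes little. The intervals, -0.829 to 0.792 and -0.481 to 0.940, leave both a strong relation and none open.

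In the same 6 relations, the log2 level in skin of the genes found only after inoculation at the other site was set against the skin response. Pearson correlations were 0.876 in Colorado (exact p = 0.0139, adjusted p = 0.0834) and 0.835 in Utah (exact p = 0.0292, adjusted p = 0.0876), with Spearman correlations of 0.771 (exact p = 0.103, adjusted p = 0.309) and 0.886 (exact p = 0.0333, adjusted p = 0.2). Without the 2 farthest toads r was 0.590 and 0.947. Neither relation passed the adjustment. Against the liver response the same level had Pearson correlations of 0.314 (exact p = 0.553, adjusted p = 0.664) and 0.398 (exact p = 0.438, adjusted p = 0.657).

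A further hypothesis was that sequence differences between the sites split 1 toad gene into 2 assembled genes, 1 per site. Genes were taken as found in the skin of 1 site when they had at least 60 counts there, were detected in at least 10 of its 12 libraries and had at most 6 counts in the 12 skins of the other site. A stricter definition (at least 5 counts in all 12 libraries and 0 at the other site) had been written first and gave 5 genes, and it was loosened after that. The definition used gave 97 genes in Colorado and 146 in Utah. Of these 243, 0% had a partner of the same assembly cluster found in the other site, against a mean of 0.103% and at most 2.06% in 1000 shuffles of cluster membership. This is within the range set beforehand as arguing against the hypothesis. It decides nothing, because only 46 of the 243 had any other tested gene in their cluster, and partners in different clusters would not be seen.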
